A study of Mus musculus with 2 samples.

How the data were processed

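RNA was measured in lower molar tooth mesenchyme of mouse embryos at embryonic day 14.5, from Osr2 heterozygous controls and Osr2 homozygous mutants. Per the labels' protocols, heads were frozen, the mesenchyme was cut out of frozen sections by laser capture microdissection, and total RNA was extracted with a column kit for small samples. The NuGEN Ovation RNA-Seq v2 kit, which amplifies small amounts of RNA into cDNA, was used to make the cDNA, again per the labels. Tissue of 3 pairs of control and mutant samples was pooled before RNA extraction, per the series' design text, and 1 library per genotype was sequenced. The background strain was mixed, and neither the sex of the embryos nor the deleted part of the Osr2 allele is given in the sources used here. Upper molars, which were dissected separately, were not analysed here. The series title speaks of wild type, while the sample label gives the control as Osr2 heterozygous; the label was followed. Per the names of the deposited files, the 2 libraries were run on different lanes, so lane and genotype cannot be told apart.

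Per the submitters' processing notes, TopHat 1.4.1, Bowtie 0.12.7 and the mouse genome build mm9 were used; the deposited files are named for Cufflinks, whose version is not given in the sources used here. Each deposited table holds 28107 RefSeq transcript rows with an RPKM value (reads per kilobase of transcript, scaled to the number of mapped reads), the mean coverage, the transcript length, the locus and a quantification status, per the file headers. The deposited RPKM values were used as the authors gave them and were not rescaled. Coverage, the mean number of reads over each base of a transcript, was deposited by the authors without scaling for library size. Among transcripts above 1 RPKM, coverage divided by RPKM was nearly constant, with a relative spread of 0.0013% in the control and 0.0016% in the mutant. It was 0.238 in the control and 1.52 in the mutant, so the mutant library was 6.38 times as deep. The values had been expected as FPKM with lower and upper bounds. The files hold RPKM without bounds, so no rule that needs bounds was used. Locus starts counted from 0 in the files (the span equalled the length in 773 of 776 transcripts under 150 bases) and are given here counted from 1, in mm9.

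Approximate read numbers were computed as coverage times length divided by 44.8 bases, taken as 1 read. That step is the mean over the 2 libraries of the median product of coverage and length among products of 20 to 66 bases. Only 26.8% of 2344 low values in the control and 25.5% of 1640 in the mutant came out within 0.1 of a whole read. Values spread evenly between whole reads would also fall that close in part, so the check supports the step little. The step also depends on the window of 20 to 66 bases, and all intervals and simulations rest on it. The read numbers are therefore estimates, and no count model was fitted to them. They correspond to about 5.31 M mapped reads in the control and 33.9 M in the mutant, with a median of 56 and 343 reads per gene tested. From them, 95% exact Poisson intervals of each RPKM and 95% Clopper-Pearson intervals of each fold were computed. These cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A fold interval that excludes 1 compares the reads of these 2 libraries, not the genotypes.

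Rows with a failed or high-data status in either library (54 rows of 18 genes) were left out and the remaining rows were summed per gene symbol, leaving 22054 genes. The main measure was the log2 ratio of mutant RPKM + 1 over control RPKM + 1, which understates differences of low genes. It was computed for 9779 genes with at least 1 RPKM in at least 1 library. Folds given with an interval are plain ratios of the RPKM values. The interval itself is that of the approximate reads scaled by depth. For genes with several transcript rows, such as Runx2 and Fgfr2, the ratio of reads can differ from the fold printed beside it. Each of 26 gene lists, and the genes within 5 Mb of Osr2, was described by the percentile of its median log2 ratio among 10000 random lists of the same size, matched in 20 bins of mean expression. A list is said to stand apart outside percentiles 2.5 to 97.5. These percentiles describe the 2 libraries and are not p-values. Lists with fewer than 5 genes tested were not placed. Exact zeros can be failed estimates: the ribosomal protein gene Rpl26 was listed at nearly 0 in the mutant. Genes at 0 in a library are therefore called listed at 0, and no fold is given for them.

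Named genes were Osr2 and Osr1; up to 15 genes per direction with the most extreme log2 ratio among genes at 5 RPKM or more and at least 2-fold apart, leaving out predicted genes, small RNAs and numbered clones; up to 4 members of each list with the largest absolute log2 ratio; and a set of tooth, bone and sex-linked genes. The comparison, the lists, this rule and the alternative settings (pseudocount, filter on low values, scaling, summing of rows, fold threshold and expression bins) were chosen before the data were examined. Genes outside this rule, further settings and 8 further lists were chosen after the files had been looked at and are named as such. Without strand information, antisense genes such as Has2as and Tsix cannot be separated from their overlapping partners, and near-identical copies such as the globin genes may share reads.

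The procedure was tested on simulated data for the mutant against control comparison over 9779 genes. Of 161 simulated 3-fold genes with at least 20 control reads, 72.7% were called at 2-fold with an interval that excluded 1, against 2 of 9579 genes simulated without a difference. The intervals held the true fold for 96.0% of 9581 genes with at least 5 control reads. Of 200 random lists without a difference, 3.5% fell outside the percentile limits, and 100% of 100 lists of 20 genes, 10 of them 3-fold higher, were found above the upper limit. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.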

Results

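The data compare 2 RNA-seq libraries of laser-captured lower molar mesenchyme from mouse embryos at embryonic day 14.5. One library came from Osr2 heterozygous controls (n = 1) and the other from Osr2 homozygous mutants (n = 1), each made from pooled tissue. There are no replicates, so the differences below describe these 2 libraries and have no replicate check. Osr2 encodes a zinc-finger transcription factor of the dental mesenchyme, and mouse embryos without it form extra teeth on the tongue side of the molars. The comparison asks which genes of the molar mesenchyme are expressed at another level without Osr2. The control library was the shallow one, with about 5.31 M mapped reads against 33.9 M in the mutant, as estimated from coverage. Of these, only about 1.43 M in the control and 7.78 M in the mutant lay on the listed transcripts. Of the transcript rows, 9136 were listed at 0 in the control and 7273 in the mutant.

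Osr2 itself was 4.23-fold lower in the mutant library (95% counting interval 3.69 to 4.86). Its level was 38.7 RPKM in the control (interval 34.8 to 43.0) and 9.16 RPKM in the mutant (8.39 to 9.97), a log2 ratio of -1.97. The gene lies on chromosome 15 from 35225867 to 35233060 in mm9 and is listed with 1 transcript of 1710 bases. The deleted part of the allele is not given in the labels, so the mutant reads can come from exons that remain, and the direction is the one the labels give. Its paralogue Osr1 was at 6.86 RPKM in the control and 8.74 RPKM in the mutant, 1.27-fold (1.0 to 1.65).

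Most genes were at similar levels in both libraries. Among the gene lists, osteogenic and dental epithelium genes lay highest in the mutant (both at percentile 100), followed by chondrogenic genes (99.7), and secreted Wnt antagonists (0.02) and erythroid genes (0.45) lay lowest. Of 9779 genes, 9614 (98.3%) lay within 2-fold, 87 were at least 2-fold higher in the mutant and 78 at least 2-fold lower, with a median log2 ratio of -0.05. Transcripts under 200 bases made up 50 of the 87 higher and 26 of the 78 lower genes, but only 94 (0.961%) of the genes tested. With a pseudocount of 0.1 the counts were 197 and 244, on the TPM scale 975 and 595 (62.1% of them higher, with a median log2 ratio of 0.08), and with the highest transcript row per gene 151 and 270 (35.9% higher), against 52.7% higher in the main setting. A counting interval that excluded 1 was found for 38 of the higher and 68 of the lower genes. These counts do not rank the directions, since higher genes are low in the shallower control library and more often short. Across genes, which are not independent replicates, log2(RPKM + 1) correlated with a Pearson r of 0.961. Of 25 sets of genes that could be placed, 9 stood apart from random lists. For sets of unrelated genes 1.25 would be expected, but members of a list can vary together, so this is no test. The libraries also differed in markers other than those of the mesenchyme. Besides the epithelial and erythroid genes, Y-linked genes differed and were listed at about 0 in the mutant.

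**Figure D1:**
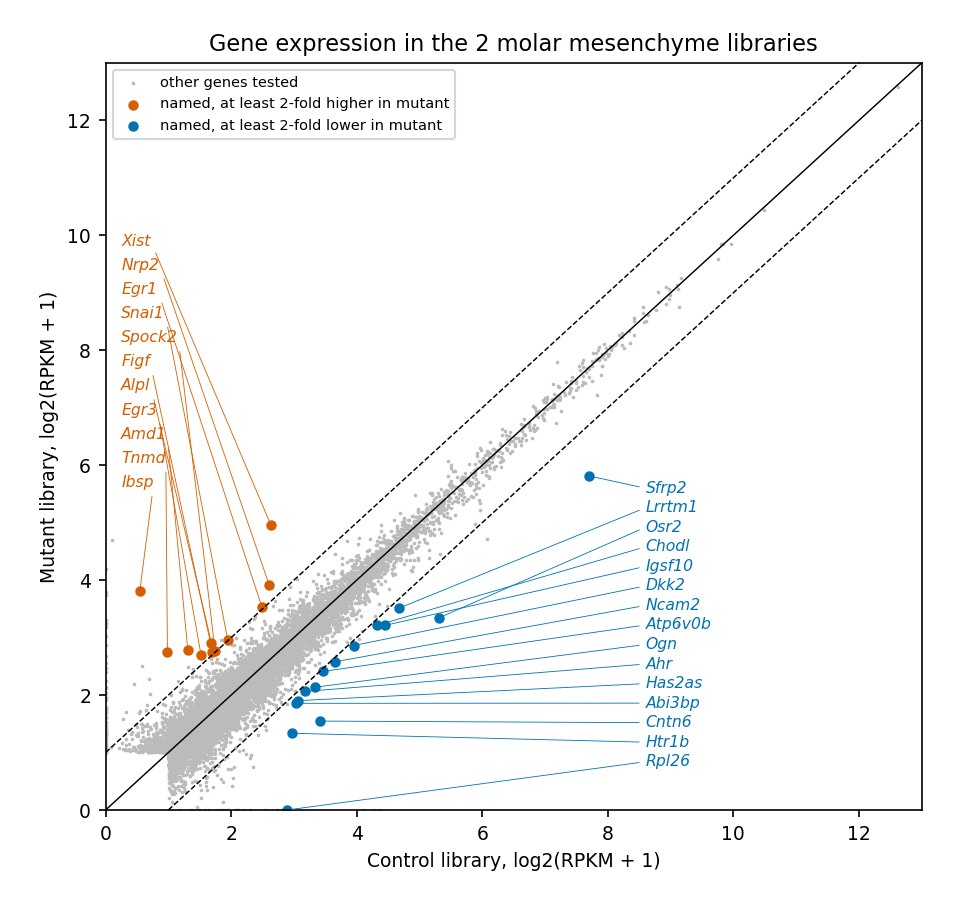
Expression of 9779 genes in the control library (x axis) and the mutant library (y axis), both as log2(RPKM + 1), 1 point per gene; the solid line marks equal values and the dashed lines 2-fold differences. Named genes at 5 RPKM or more and at least 2-fold apart are coloured, 11 higher and 15 lower in the mutant, with Sfrp2 and Osr2 below the lower line and Ibsp and Xist above the upper line.

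Among genes at 5 RPKM or more, 24 were at least 2-fold higher and 26 at least 2-fold lower in the mutant. Sfrp2, which encodes a secreted Wnt-binding protein, was the most abundant of the named lower genes. Cntn6, a contactin of the immunoglobulin superfamily, was 5.03-fold lower (4.13 to 6.14), at 9.68 RPKM in the control and 1.92 RPKM in the mutant. The serotonin receptor gene Htr1b was 4.51-fold lower (2.94 to 6.73). Igsf10 was at 20.8 and 8.26 RPKM, and Ncam2, a neural cell adhesion molecule, at 11.5 and 4.97 RPKM. Ogn and Abi3bp, both encoding extracellular matrix proteins, were 2.68-fold (2.16 to 3.33) and 2.76-fold (2.26 to 3.26) lower. Lrrtm1, Chodl, Atp6v0b and Ahr, the aryl hydrocarbon receptor gene, were 2.36-fold, 2.30-fold, 2.32-fold and 2.54-fold lower. Has2as was 2.68-fold lower (1.49 to 4.70), on 19 control reads and without a means to separate it from Has2. Rpl26 was at 6.41 RPKM in the control and listed at nearly 0 in the mutant.

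On the higher side, Ibsp, which encodes bone sialoprotein, had the largest ratio. Tnmd, the tendon and ligament gene tenomodulin, was 5.88-fold higher (2.76 to 14.5), at 0.979 RPKM in the control and 5.76 RPKM in the mutant. Nrp2, a co-receptor for class 3 semaphorins and VEGF, was 2.79-fold higher (2.35 to 3.27). With only its highest transcript row, the log2 ratio of Nrp2 was 1.06 against 1.32 with its rows summed. Amd1, an enzyme gene of polyamine synthesis with a closely similar copy in the mouse genome, was 3.99-fold higher (2.69 to 6.25). Figf, which encodes VEGF-D, was 2.54-fold higher (1.68 to 4.18), Spock2 2.46-fold (1.84 to 3.35) and the transcription factor gene Snai1 2.36-fold (1.56 to 3.74). Egr1 and Egr3 were 2.28-fold (1.81 to 2.94) and 2.92-fold (1.72 to 5.44) higher.

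Genes listed as secreted Wnt antagonists, which include the membrane inhibitors Kremen1 and Apcdd1, were lower in the mutant library as a group. Of 9 genes tested, 2 were at least 2-fold lower, 5 had a counting interval below 1 and none had 1 above it; the median log2 ratio of -0.35 lay at percentile 0.02. Sfrp2, on chromosome 3 from 83570243 to 83578236, was at 208 RPKM in the control and 55.2 RPKM in the mutant, 3.76-fold lower (3.56 to 3.96). Dkk2, a secreted ligand of the Wnt co-receptors, on chromosome 3 from 131748256 to 131843268, was 2.31-fold lower (2.02 to 2.66), at 14.5 and 6.27 RPKM. Sfrp1 was 1.61-fold lower (1.48 to 1.75) and Wif1 1.51-fold lower (1.14 to 1.96). Frzb, another Wnt-binding protein, was at 35.5 and 35.2 RPKM, a ratio of 0.99 (0.91 to 1.09).

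Genes that respond to Wnt signalling had a median log2 ratio of 0.12, at percentile 97.7 of the random lists. Of 11 tested, 9 had a log2 ratio above 0, 3 had an interval above 1 and none was 2-fold apart. Lef1, a transcription factor of the Wnt pathway, was 1.78-fold higher (1.42 to 2.24), Tcf7 1.72-fold (1.13 to 2.72) and Ccnd1 1.34-fold (1.14 to 1.59). Axin2, a feedback target of the same pathway, was at 9.06 and 8.86 RPKM, a ratio of 0.98 (0.84 to 1.14). The group stayed above the limit under only 3 of 9 alternative settings, with percentiles from 92.4 to 99.9. Dental epithelium, in which Lef1 is also expressed, had higher markers in the same library (percentile 100). Whether it accounts for the fold of Lef1 was not tested. Wnt ligands and R-spondins did not stand apart (5 tested, percentile 19.4), except on the lower side under 2 of 8 alternatives (2.19 without the filter and 1.37 on the TPM scale), with Rspo3 at 14.6 and 18.4 RPKM and Wnt2 at 1.15 and 0.495 RPKM.

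Bone-forming genes were on balance higher in the mutant library, while the abundant matrix genes among them were not. Of 13 osteogenic genes tested, 4 were at least 2-fold higher and none 2-fold lower, 8 had an interval above 1 and 4 below 1, and the median log2 ratio of 0.51 lay at percentile 100. Ibsp, on chromosome 5 from 104728306 to 104740491, was at 0.459 RPKM in the control (0.156 to 1.12, about 5 reads) and 13.0 RPKM in the mutant, 28.4-fold higher (11.6 to 83.6). Sp7, which encodes the osteoblast transcription factor osterix, on chromosome 15 from 102187608 to 102196702, was 6.33-fold higher (3.19 to 16.7), at 0.607 and 3.84 RPKM. Alpl, the alkaline phosphatase gene of mineralising tissue, was 2.93-fold higher (2.01 to 4.33). Ifitm5, a membrane protein gene of osteoblasts, was listed at 0 in the control and 1.12 RPKM in the mutant. Runx2, the transcription factor that directs osteoblast formation, was 1.84-fold higher (1.66 to 2.03), at 13.4 and 24.7 RPKM. With only the highest transcript row of Runx2, its log2 ratio was 0.60 against 0.83 with its rows summed. The 4 members with an interval below 1, named after their values were seen, were Postn (226 and 149 RPKM), Col1a2 (86.3 and 73.4 RPKM), Sparc (1.14-fold lower, from 91.3 RPKM in the control) and Phex (1.78 and 1.05 RPKM). Spp1 and Bglap, genes of mature bone matrix, were listed at 0 in the control and at 0.0992 and 0.147 RPKM in the mutant, below the filter. The control levels of Ibsp and Sp7 rest on 5 and 7 reads.

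**Figure D2:**
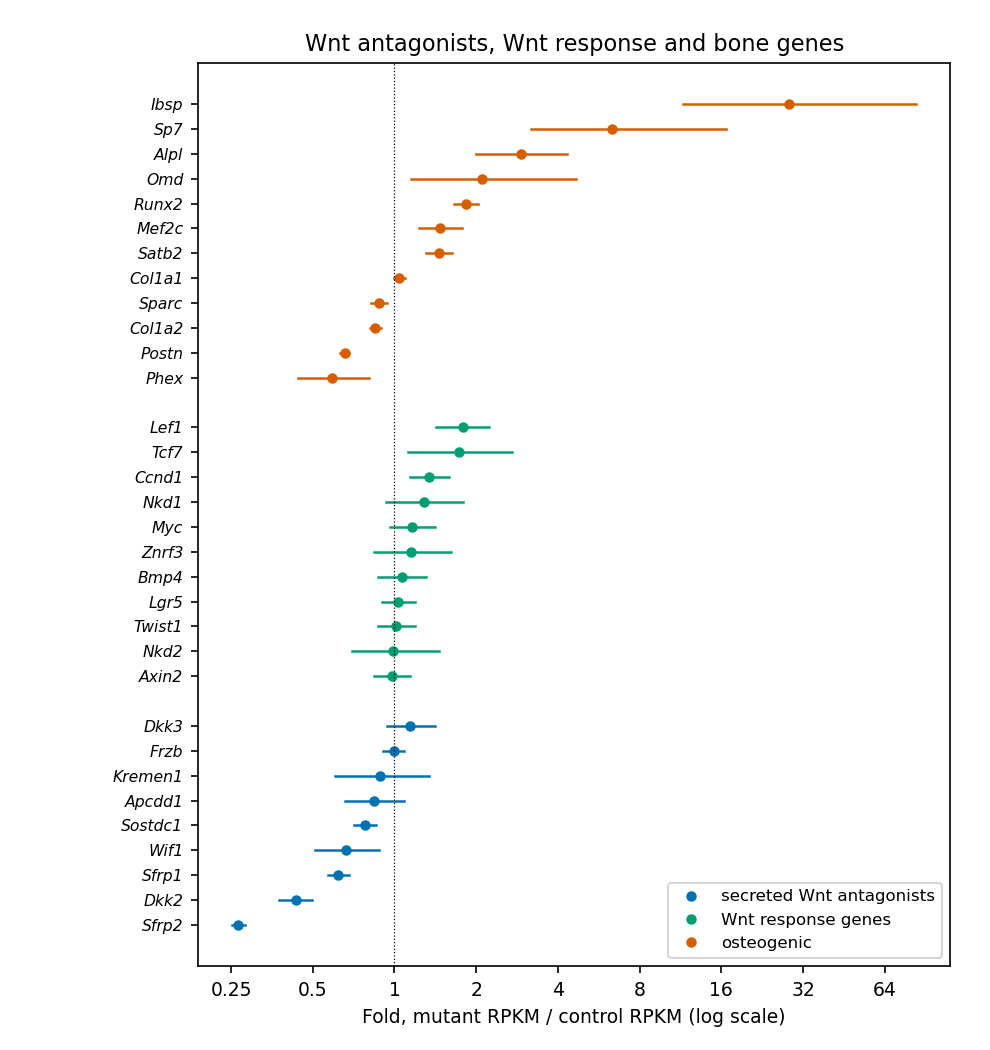
Fold of mutant over control RPKM (x axis, log scale) for members of 3 gene lists with a value above 0 in both libraries; points are the ratios of the 2 libraries, bars the 95% counting intervals and the dotted line equal levels. Sfrp2 and Dkk2 lie below 0.5 among the Wnt antagonists, the Wnt response genes lie near 1 with Lef1 at 1.78, and Ibsp, Sp7 and Alpl lie above 2 among the osteogenic genes.

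The few cartilage genes that passed the filter were also mostly higher in the mutant, though at low levels. Of 18 chondrogenic genes on the list, only 5 could be tested. Of these, 4 had an interval above 1, and the list lay at percentile 99.7. The cartilage collagen gene Col2a1 was 1.95-fold higher (1.59 to 2.38), at 4.05 and 7.90 RPKM, Sox6 1.77-fold (1.37 to 2.33) and Sox9 1.34-fold (1.08 to 1.69). Hapln1 was at 2.66 and 2.06 RPKM. The list no longer stood apart under 2 of 8 alternatives, at percentile 66.8 without the filter on low values and 76.7 on the TPM scale.

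The BMP pathway list lay at percentile 97.7, while its best known dental members were nearly equal in both libraries. Msx1, the transcription factor required for molar development beyond the bud, was at 40.0 and 36.8 RPKM, a ratio of 0.92 (0.83 to 1.02). Bmp4 was at 10.4 and 11 RPKM, 1.07-fold (0.87 to 1.31). Higher in the mutant were Bmp2, 2.35-fold (1.63 to 3.58), Bmp3, 1.98-fold (1.42 to 2.92), and Bmper, 2.26-fold (1.42 to 3.91). Id4 was 2.45-fold lower (1.60 to 3.74). Of 24 genes tested, 5 had an interval above 1 and 6 below 1, and the list stood apart under 4 of 9 alternatives. With a filter of 5 RPKM it lay near the middle of the random lists (percentile 40.7).

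The other signalling lists held genes on both sides and did not stand apart. In the FGF pathway (16 tested, percentile 76.1), the receptor gene Fgfr2 was 1.99-fold higher (1.65 to 2.33) and the ligand gene Fgf10 2.14-fold lower (1.58 to 2.86). With only the highest transcript row of Fgfr2, its log2 ratio was 1.63 against 0.88 with its rows summed. Fgf3 was at 0.164 RPKM on 1 control read and 0.624 RPKM in the mutant. In the Hedgehog pathway (11 tested, percentile 8.79), the receptor and target gene Ptch1 was 1.49-fold higher (1.31 to 1.70) and Gli1 1.64-fold (1.16 to 2.35), while Gas1 was 1.76-fold lower (1.55 to 1.99). Shh, made by the dental epithelium, was listed at 0 in the control and 0.175 RPKM in the mutant. Inhba, the activin subunit gene of dental mesenchyme, was at 40.7 and 36.1 RPKM, 1.13-fold lower (1.0 to 1.27), in a TGF-beta and activin list at percentile 49.6. In the Notch pathway (8 tested, percentile 82.4), the target gene Hey1 was 2.18-fold higher (1.55 to 3.08). Epithelial markers were also higher in the mutant library (median fold of 19 markers 1.43, range 0.68 to 3.12). Epithelium also expresses Bmp2 and Fgfr2, but whether it accounts for their folds was not tested.

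Transcription factors of the dental mesenchyme went both ways (22 tested, 6 with an interval above 1 and 8 below 1, percentile 63.3). Pax9, required for tooth development past the bud, was 1.56-fold lower (1.45 to 1.69), at 61.7 and 39.4 RPKM. Twist2 was 2.79-fold higher (1.56 to 5.80) and Dlx3 4.73-fold higher (1.81 to 13.5), from 1.62 and 0.332 RPKM in the control. With a filter of 5 RPKM, which leaves out these low genes, the list lay at percentile 1.03, while without a filter it lay at 95.6 and on the TPM scale at 96.9, both inside the limits.

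Genes of axon and cell guidance (Eph receptors, ephrins, semaphorins, Slits and their receptors, in 1 list) had a lower median in the mutant library, with members on both sides. Of 25 tested, 11 had an interval below 1 and 3 above 1, and the list lay at percentile 1.69. The receptor genes Epha3 and Epha7 were 1.90-fold (1.78 to 2.03) and 1.89-fold (1.80 to 2.03) lower, and Slit3 1.65-fold lower (1.47 to 1.84), against the higher Nrp2. The list no longer stood apart under 3 of 9 alternatives, which gave percentiles of 12.0, 3.35 and 5.95. Of 30 extracellular matrix genes, 15 had an interval below 1 and 6 above 1, at percentile 2.76, just inside the limits, and under 4 of 9 alternatives the list lay outside them (1.63, 2.07, 2.41 and 1.93). Besides Ogn, the lysyl oxidase gene Lox was 2.23-fold lower (1.83 to 2.72), Dcn, the decorin gene, 1.74-fold (1.55 to 1.97) and Fbln5 1.79-fold (1.47 to 2.17).

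**Figure D3:**
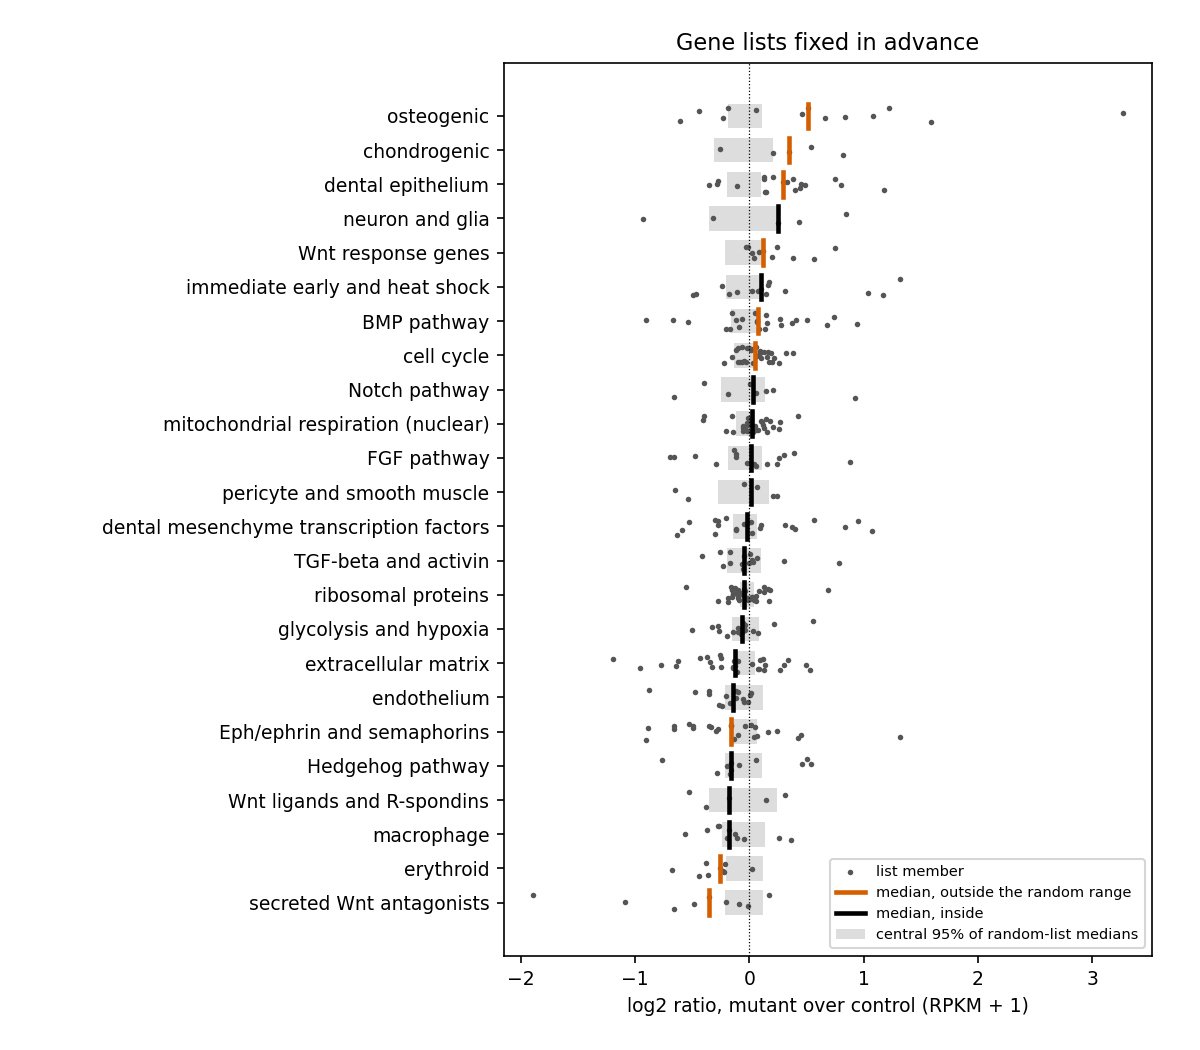
Log2 ratio of mutant over control RPKM + 1 (x axis) for the members of 24 gene lists (rows), 1 point per gene; vertical bars are list medians, coloured where they lie outside the grey band, which spans the central 95% of medians of matched random lists. The osteogenic median of 0.51 lies farthest to the right and the median of -0.35 for secreted Wnt antagonists farthest to the left.

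Among markers of other cell types, epithelial genes were higher and erythroid genes lower in the mutant library. Of 19 dental epithelium genes, 9 had an interval above 1 and 1 below 1. Krt17 was 3.12-fold higher (1.74 to 6.08), Krt18 2.60-fold (1.23 to 7.72) and Perp 1.87-fold (1.34 to 2.73). Of 9 erythroid genes, 6 had an interval below 1 and none above, among them Hba-a1 at 143 and 106 RPKM and Hbb-y at 564 and 433 RPKM. Endothelial (16 tested, percentile 11.5), macrophage (11 tested, 9.25) and pericyte and smooth muscle genes (6 tested, 71.6) did not stand apart, with the endothelial gene Emcn 2.17-fold lower (1.47 to 3.06). With only the highest transcript row of Emcn, its log2 ratio was -1.90 against -0.88 with its rows summed. In the neuron and glia list (5 tested, percentile 97.3, and 98.6 without the filter), Nefl was 2.19-fold higher (1.39 to 3.46) and Gfra3 5.52-fold lower (2.62 to 12.0). Only 3 skeletal muscle genes were tested, and none of 15 Hox genes, a family known to be silent in jaw mesenchyme, passed the filter.

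Transcript levels of proliferation and general metabolism genes differed little. All 30 cell cycle genes lay within 2-fold, with a median log2 ratio of 0.05 at percentile 98.2, and Kif20a at 1.38-fold (1.08 to 1.78). Under 2 alternatives the cell cycle list did not stand apart, at percentiles 96.8 and 88.5. Ribosomal protein genes (35 tested, percentile 21.3), nuclear genes of mitochondrial respiration (30 tested, 90.8) and glycolysis and hypoxia genes (18 tested, 30.2) did not stand apart. In the immediate early and heat shock list (15 tested, percentile 96.7, above the limit at 98.2, 99.5 and 99.6 under 3 of 9 alternatives), Egr1, Egr2 and Egr3 were at least 2-fold higher, with Egr2 at 0.624 and 3.05 RPKM.

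Sex-linked genes differed between the pools. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 3.28, 2.71, 2.15 and 1.81 RPKM in the control. Ddx3y, Kdm5d and Eif2s3y were listed at 0 in the mutant and Uty at nearly 0. Xist, the RNA expressed from the inactive X chromosome, was at 5.21 RPKM in the control and 30.0 RPKM in the mutant. Its antisense gene Tsix was listed at about 0 and at 0.0372 RPKM. Tnmd and Figf, named above as higher, also lie on chromosome X, whose 371 genes tested had a median log2 ratio of -0.10. The 35 genes tested within 5 Mb of Osr2, where mutants can share a haplotype linked to the allele, did not stand apart (percentile 81.6). Mir599, named here after its value was seen, was the member at least 2-fold apart, listed at 0 in the control and 1.74 RPKM in the mutant.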

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

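In this part, the simulation of the 2-fold counts and the test of X-linked genes were set before their results were seen. The tests of short transcripts, of the bone genes and of the expected Y-linked reads were chosen only after the results were seen.

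Of the 18 genes with rows left out of the comparison for their quantification status, 2 were at least 2-fold higher in the mutant in those rows, 8 were at least 2-fold lower, all 8 listed at 0 in the mutant, and 8 lay within 2-fold. Cnot2 was at 11.9 RPKM in the mutant, while its control rows had a failed status and were listed at 0. Rps27 was at 944 RPKM in the mutant, in rows with a failed status, against 459 RPKM in the control. The predicted gene Gm9846, which shares the Rps27 locus, was at 554 RPKM in the control and 8.29 RPKM in the mutant and is among the 78 genes counted as lower. Together the locus had 1013 RPKM in the control and 952 RPKM in the mutant.

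The number of genes at least 2-fold apart, 87 higher and 78 lower, has as its main technical explanations the shallow control library and very short transcripts. In 100 simulated pairs without a difference, at the real depths, a median of 49 genes (range 32 to 62) were 2-fold apart. By direction, the simulated medians were 31 higher and 18 lower. Counting error of independent reads alone thus does not reach the 165 observed. Among transcripts of 200 bases or more the simulated median was 5 against 89 observed. Short transcripts were only 94 (0.961%) of the genes tested but made up 46.1% of the genes 2-fold apart. Most genes 2-fold apart in the simulated pairs were short as well. Counting error and recovery from fragmented cDNA both stay open for that part of the count. Uneven amplification, sequencing lane and genotype differ together here and cannot be told apart without replicates.

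The osteogenic genes, with 4 of 13 at least 2-fold higher and a median log2 ratio of 0.51, are the group a biologist may most want to follow up. Counting error of independent reads is argued against, since the highest osteogenic median in 100 simulated pairs without a difference was 0.0658. Amplified reads are not independent molecules, so a larger sampling error in these libraries was not excluded. Bone-forming tissue at the edge of the dissected mutant mesenchyme cannot be told apart from expression within it: the abundant matrix genes Col1a1, Col1a2, Sparc and Postn had a median log2 ratio of -0.21, but their high level in jaw mesenchyme would hide a small share of bone. The loss of Osr2, and an effect of embryo sex on these genes, of which 12 of 13 are autosomal, stay open as untested.

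Y-linked genes were listed at about 0 in the mutant pool, and Xist was higher there. At the control level, 1506 reads of the 4 Y-linked genes would be expected in the mutant library, so counting error is argued against. The 4 X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, had a median log2 ratio of 0.13, with 3 of 4 above 0, the direction that a mutant pool of female embryos and a control pool with male embryos would give. Y-linked RNA of these 4 genes was thus found in the control pool (about 236 reads) and about none in the mutant pool. A different sex mix of the pools is the explanation these values go with, although the labels do not give the sex. Differences of other genes between the libraries may then include differences between the sexes, which these 2 libraries cannot separate from genotype.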

How the results depend on the processing

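In this part, the alternatives without chromosomes X and Y, with counting intervals, without transcripts under 200 bases, with the mutant library thinned, and without Ibsp or Sfrp2 were chosen only after the results were seen; the others had been chosen in advance. No paired analysis was possible because each genotype has 1 library. The alternative on RPKM bounds, chosen in advance, was not run, since the files hold none. Osr2 stayed between log2 ratios of -2.07 and -1.89 under 8 alternatives. The osteogenic list (percentile 100 under 10 alternatives), the secreted Wnt antagonists (0 to 2.1 under 10, including without Sfrp2), dental epithelium (99.97 to 100) and the erythroid list (0.04 to 0.775) kept their side under the alternatives run. Of 220 list values under an alternative, 191 gave the call of the main setting, and none of the named genes at least 2-fold apart changed direction. Of 949 values of single named genes, 42 moved by more than their counting error. Most of these were on the TPM scale or with the pseudocount of 0.1, and 6 with the highest row per symbol. With that row, the log2 ratios of Fgfr2 (1.63), Emcn (-1.90), Xist (2.55) and Pdgfrb (0.56) became larger in size. Those of Runx2 (0.60) and Nrp2 (1.06) became smaller. The depth of the control library limits low genes: with the mutant thinned to it, 100 genes were higher and 116 lower, sharing 59 and 66 with the main counts.

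With a pseudocount of 0.1, 197 genes were higher and 244 lower, because low genes are damped less; BMP moved to percentile 97.0 and no longer stood apart, and immediate early genes, at 98.2, did. Without the filter, Wnt ligands (2.19), extracellular matrix (1.63), immediate early genes (99.5) and neuron and glia (98.6) stood apart, while Eph and semaphorins (12.0) and cartilage (66.8) did not. With a filter of 5 RPKM, 3909 genes remained, 24 higher and 26 lower. BMP (40.7), Wnt response (92.4), Eph and semaphorins (3.35) and cell cycle (96.8) no longer stood apart, and dental transcription factors (1.03) did. On the TPM scale 13999 genes passed the filter, because values are larger there, and 975 were higher and 595 lower; BMP (96.9), Eph and semaphorins (5.95) and cartilage (76.7) no longer stood apart, while Wnt ligands (1.37), extracellular matrix (2.07) and immediate early genes (99.6) did. That scale shifts plain log2 ratios, without a pseudocount, by 0.14, and by 0.05 without the rows left out for their status; ratios with the pseudocount move by other amounts, most in low genes. Centring on genes of 10 RPKM or more put Wnt response at 96.7 and extracellular matrix at 2.41, and upper-quartile scaling put them at 95.9 and 1.93. With the highest row per symbol, 151 genes were higher and 270 lower, with BMP at 97.0, Wnt response at 97.2 and cell cycle at 88.5. With 5 expression bins Wnt response was at 97.3. Without chromosomes X and Y, BMP was at 97.1 and Wnt response at 97.2. A counting interval that excludes 1 left 38 higher and 68 lower genes. Leaving out transcripts under 200 bases left 37 higher and 52 lower, and a 4-fold threshold 21 higher and 15 lower. Where no reason is given, the cause was not tested.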

Other observations

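In this part, the 7 gene lists, the tests on them and the Wnt test were chosen only after the results were seen.

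Cell adhesion genes of the immunoglobulin family were listed because Cntn6, Igsf10 and Ncam2 had been seen to be lower. The other 9 members tested did not stand apart, at percentile 47.4 with a median log2 ratio of -0.05. Of these 9, 4 had a counting interval below 1 and none above 1. Of 9 cadherin and protocadherin genes, 6 had an interval below 1 and none above 1, at percentile 4.71, just inside the limits. Cdh11, the cadherin of mesenchyme, was at 77.4 RPKM in the control and 61.6 RPKM in the mutant, and Pcdh9 at 2.72 and 1.18 RPKM. Among transcription factors of the epithelial to mesenchymal transition (9 tested, percentile 93.7), Snai1 and Twist2 were at least 2-fold higher, while Prrx1 was at 151 and 122 RPKM.

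Small leucine-rich proteoglycans divided (8 tested, percentile 67.4). Ogn, Dcn and Bgn, the last at 34.7 and 22.1 RPKM, were lower in the mutant, while Lum was at 68.1 and 74.2 RPKM and Omd at 1.12 and 2.35 RPKM. Retinoic acid pathway genes (10 tested, percentile 46.9) and imprinted growth genes (13 tested, percentile 16.1) did not stand apart. Crabp1 was at 24.9 and 35.1 RPKM, Aldh1a2 at 6.47 and 9.60 RPKM, and Igf2 at 137 and 141 RPKM. Lars2 was listed at 8006 RPKM in the control and, with a high-data status, at 0 in the mutant, and was left out.

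Tnmd, Egr1 and Egr2, which are expressed in tendon, were at least 2-fold higher and prompted a list of tendon genes. Tendon-forming cells among the mutant mesenchyme may be the source. Egr1 and Egr2 are also on the immediate early and heat shock list, where Egr3 was 2.92-fold higher, so they are not particular to tendon. Tnmd had about 7 control reads and lies on chromosome X. The other 3 members tested, Mkx at 3.56 and 5.51 RPKM, Fmod at 0.428 and 1.02 RPKM and Tgfbi at 8.90 and 9.14 RPKM, had a median log2 ratio of 0.50, between the bounds of 0.3 and 0.5 set for the test, so it decided nothing. Scx, the tendon transcription factor, was at 0.570 and 0.793 RPKM, below the filter.

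A hypothesis of a different kind is that Wnt response genes are higher where secreted Wnt antagonists are lower. The Wnt response list lay at percentile 97.7, above the upper limit, but stayed there under only 3 of 9 alternatives, and Axin2 had a ratio of 0.98. The test therefore leaves the hypothesis undecided in these libraries.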
